A study of Mus musculus with 4 samples.

How the data were processed

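Perihematomal brain tissue of mice was sampled after a sham procedure and 6 h, 24 h and 72 h after intracerebral hemorrhage, with 1 library per group. Nuclei were isolated with a kit and sequenced with 10x Chromium 3′ v3.1 chemistry, per the labels. The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, made with Cell Ranger 5.0.1 on mm10 per the submitters' processing notes, while the file headers name Cell Ranger 4. The deposited matrices were unfiltered, with 6794880 barcodes and 32285 genes in each library. The upstream choice of reads and the time from the sham procedure to sampling are not given in the sources used here. The libraries held 202490974 (sham), 168997190 (6 h), 182158056 (24 h) and 201662402 (72 h) UMIs.

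Analyses were run in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. The floors, the doublet rule, the clustering settings, the markers, the gene lists, the rule for naming genes and most alternatives were set before the data were examined. Barcodes were called as nuclei with at least 700 detected genes and at most 5% of UMIs from mitochondrially encoded genes. A floor of 500 genes had been planned, with a rise in steps of 100 in all libraries if over 15000 barcodes passed in any. At 500 genes 52384 sham barcodes passed, against 12914, 14372 and 12555 at 6, 24 and 72 h, so the floor was raised. This gave 14705, 12545, 13559 and 11238 barcodes from sham to 72 h, after removal of 13, 16, 13 and 195 for mitochondrial UMIs. Doublets were scored with Scrublet in each library, and the 1730, 1259, 1471 and 1010 barcodes with the highest scores were removed, 0.8% of the nuclei per 1000 called. The automatic threshold would have removed 718, 699, 818 and 622. The 12975, 11286, 12088 and 10228 nuclei kept had medians of 3149, 3523.5, 3373 and 3824 genes and held 64.3%, 73.4%, 70.99% and 72.98% of the UMIs in barcodes of at least 10 UMIs. With n UMIs summed, the counting error of a level is near 1 over the square root of n, and its exact interval is printed where a level or fold rests on few UMIs.

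The 4 libraries were clustered together without integration: counts were scaled to 10000 per nucleus and logged, 3000 variable genes were chosen within libraries, and 30 principal components, 15 neighbors and Leiden resolution 1.0 were used. A cluster took the class whose markers stood highest over the clusters, given at least 3 markers detected in 10% of its nuclei and at 2 times the median cluster, and 40% of the markers for classes other than neurons. It stayed unnamed when its 10 leading genes (at least 50 UMIs, 5 CPM added) held more markers of another class than of its own, or when its median UMIs were under the library median divided by 3 and no leading gene was its own marker. Non-neuronal clusters of at least 100 and under 1000 nuclei were clustered a second time. This naming rule was worked out in several passes with the clusters and class counts in view. Leading genes were first ranked by fold over all other nuclei, which left oligodendrocyte clusters 2 and 5 unnamed, and then by fold over the median cluster. Names such as microglia-like describe marker content only, and labels of libraries were never inferred from values.

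Class shares were taken over named nuclei (10958, 10630, 11746 and 9610) with exact 95% intervals. Classes with at least 50 nuclei in sham and in the library compared were compared, so no endothelial, mural or fibroblast-like class was, and gene lists set for those classes alone were not measured. UMIs were summed per library and class and scaled to CPM over genes other than mitochondrially encoded and hemoglobin genes. Fold intervals are exact, from the binomial split of the 2 counts. A library at 0 UMIs was set to 3 and the fold given as a bound, while folds on counts above 0 and under 3 are printed as raw ratios. The plan had set any count under 3 to 3 and given a bound. These raw ratios thus depart from the plan and lie further from 1 than the planned bounds. For ranking genes and for folds under other settings, any count under 3 was set to 3. List medians used members with at least 20 UMIs in the 2 libraries together and 0.5 added counts, with intervals from redrawn Poisson counts, and a percentile among 10000 random lists of the same size matched in 20 expression bins, which describes these libraries only. Medians were also taken with members under 3 UMIs at their bound. Mx1 and Clec7a had no entry under these symbols. Shares of nuclei with a UMI used nuclei thinned to 1000 UMIs.

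Named genes were, for each comparison and class, the 2 with the largest fold higher and the 1 with the largest fold lower among genes with at least 50 UMIs where higher, at least 2 times the CPM of empty droplets of 10 to 100 UMIs and at least 0.1 of the highest class of that library, and up to 4 members with the largest log2 ratio in each list described. Unnamed gene models, mitochondrially encoded, hemoglobin, X-inactivation and Y-linked genes were left out, and some genes that the rule names are not reported here. Which lists to describe, the genes thinned, the genes of cluster 29 and the genes repeated from other libraries were chosen after their values were seen. The range of 10 to 100 UMIs held 19016, 12707, 10392 and 10482 barcodes, so barcodes of over 200 UMIs and under 600 genes were added afterwards as a second profile of free RNA. The free RNA share of each class was estimated from markers of other classes.

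Steps were tested on simulated counts. In microglia-like nuclei at 6 h, 50 genes raised 4-fold among 32264 were recovered at a median of 3.92-fold. In D1-type nuclei at 6 h 95.45% of the intervals of unchanged genes covered their expected ratio. Both values allow for the shift that the changed genes made in the totals. Both libraries were drawn as Poisson counts from the same sham sums. Such coverage was thus built in and says nothing about spread between animals. A list of 20 genes raised by 1 on the log2 scale came back at 1.11 in microglia-like nuclei at 6 h, above all random lists. The naming rule gave 95.2% of 3150 simulated nuclei their own class over 32285 genes, and 50% for neuroblasts. These nuclei were drawn from summed sham and 24 h profiles of the classes that the same rule had named. High recovery was thus largely built in, and it cannot show that the names of the real clusters are right. With 1 library per group no test between conditions was made. Alternatives tried were gene floors of 300 and 1000, an order-of-magnitude rule on UMIs, no doublets removed or the automatic threshold, at most 1% mitochondrial UMIs, resolutions of 0.5 and 2.0, each library clustered alone, shares of all kept nuclei, CPM over all genes, median-of-ratios scaling, subtraction of free RNA, thinning to 1000 or 500 UMIs, no minimum count and 5 added counts. Added after seeing the data were cluster 29 counted as microglia, no second clustering, the first ranking of leading genes, the second free RNA profile, the 72 h library as the baseline and neuron clusters matched between libraries.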

Results

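The series asked how the cells of the tissue around a hematoma differ over the first days after an intracerebral hemorrhage, a bleed into the brain, in mice. Nuclei from that tissue were sequenced on a droplet platform that counts transcripts as unique molecular identifiers (UMIs), in 1 library each for sham, 6 h, 24 h and 72 h after hemorrhage. The libraries held 202490974 UMIs for sham, 168997190 for 6 h, 182158056 for 24 h and 201662402 for 72 h. In that order, 12975, 11286, 12088 and 10228 nuclei were kept, with medians of 8788, 9748.5, 9171.5 and 12390 UMIs per nucleus. With 1 library per group nothing could be tested, and each comparison is between libraries. The 95% intervals in parentheses are exact for levels, folds and shares, and cover counting error only, not differences between animals. Levels (CPM) are counts summed over the nuclei of a class and scaled to a common total, and the value of a gene list is the median log2 ratio of its measured members to the library labelled sham.

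The library labelled sham held leukocyte-like and dividing microglia-like nuclei at high shares, and its label is therefore repeated as given. Macrophage-like nuclei made up 2.08% (1.82 to 2.37) of its named nuclei, against 0.00941%, 0.0766% and 0.614% (0.468 to 0.791) at 6, 24 and 72 h. T or NK cell-like nuclei made up 1.497% (1.28 to 1.74), against 0.0470%, 1.11% and 0.676%. Top2a, an enzyme that untangles DNA in dividing cells, had a UMI in 10.7% (8.72 to 12.9) of its microglia-like nuclei after each nucleus was thinned to 1000 UMIs, against 0.559%, 0.2997% and 3.88% (2.80 to 5.23) at 6, 24 and 72 h. Without thinning these shares were 18.5%, 0.559%, 1.10% and 6.71%. Excitatory neuron-like nuclei, which should lack Top2a, gave thinned shares of 0.0407%, 0, 0.0238% and 0.0326%. Median depths were 3371, 2428, 3211 and 4011.5 UMIs in the microglia-like nuclei and 15804, 14473.5, 15528.5 and 20231 in the excitatory neuron-like nuclei. The time from the sham procedure to sampling is not given in the sources used here, so the 72 h library also served as a baseline for the 6 h and 24 h libraries.

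Make-up of the tissue differed between the libraries in glia and in the neurons of the striatum. Microglia-like nuclei, the resident immune cells of the brain, made up 8.13% (7.63 to 8.66) of named nuclei in the library labelled sham, 1.68% (1.45 to 1.95) at 6 h, 8.53% (8.03 to 9.05) at 24 h and 11.01% (10.4 to 11.7) at 72 h. Their ratios to sham were 0.207 (0.175 to 0.243), 1.05 (0.958 to 1.15) and 1.35 (1.24 to 1.48). Oligodendrocyte-like nuclei, the myelinating cells, made up 15.7%, 23.1%, 27.2% and 17.1%, with ratios of 1.47 (1.38 to 1.56), 1.73 (1.63 to 1.84) and 1.09 (1.02 to 1.16). Astrocyte-like nuclei made up 0.575% in the library labelled sham and 3.75% at 6 h, a ratio of 6.53 (4.995 to 8.66), and 0.766% and 1.06% at 24 and 72 h, ratios of 1.33 (0.955 to 1.87) and 1.85 (1.34 to 2.57). D1 spiny projection neuron-like nuclei, which carry a dopamine receptor of the direct striatal pathway, made up 20.7%, 9.60%, 8.37% and 14.5%, and the D2 type of the indirect pathway 10.2%, 5.72%, 3.88% and 8.44%. Excitatory neuron-like nuclei made up 22.4%, 33.7%, 35.8% and 31.9%, and inhibitory interneuron-like nuclei 16.0%, 19.6%, 12.4% and 10.6%. Oligodendrocyte precursor-like nuclei made up 1.88%, 2.48%, 1.17% and 2.75%, and neuroblast-like nuclei 0.712%, 0.273%, 0.698% and 1.19%. Endothelial, mural and fibroblast-like nuclei were too few to compare.

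Different clusters held the glial classes in different libraries. Oligodendrocyte-like nuclei of sham and 72 h lay mostly in cluster 1, those of 6 h in cluster 5 and those of 24 h in cluster 2. Microglia-like nuclei of sham and 72 h lay mostly in cluster 9 and those of 6 h and 24 h in cluster 14. Astrocyte-like nuclei of 6 h lay in clusters 21.0, 21.2, 21.3, 21.4 and 21.5, those of sham and 72 h mostly in 21.1 and 21.6, and 43 of the 90 of 24 h in 21.7. Oligodendrocyte precursor-like nuclei of 6 h lay mostly in clusters 18.2, 18.3, 18.5 and 18.7 (43, 82, 67 and 58 nuclei), which held 1 nucleus of sham, while sham had 123 and 61 nuclei in 18.0 and 18.1. Those of 24 h lay mostly in 18.8 and 18.2 (57 and 56 nuclei), which held 0 nuclei of sham, and Hmga2 was among the leading genes of 18.8. Cluster 18.5 had no marker of its class among its leading genes. Unnamed nuclei made up 15.5% of the kept nuclei in the library labelled sham, 5.81% at 6 h, 2.83% at 24 h and 6.04% at 72 h. Cluster 10, with a median of 1158 UMIs, gave most of them in sham, 11.1% of kept nuclei. Cluster 29 held 3.69% (3.35 to 4.05) of the kept nuclei at 6 h and 0, 0.0662% and 0 in sham, 24 h and 72 h. Microglia was the best-ranked class of each of its parts. The parts stayed unnamed because too few markers were detected, or UMIs were low with no own marker among the leading genes.

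The shares depended on how nuclei were called, clustered and named, and the naming rule was worked out while the clusters were in view. Among the ratios to sham that turned or moved by over 1.5-fold were, for oligodendrocyte-like nuclei, 0.931, 1.12 and 0.772 at 6, 24 and 72 h with the automatic doublet threshold, 0.963, 1.01 and 0.644 with each library clustered alone, 1.00 at 24 h and 0.884 at 72 h with an order-of-magnitude rule for calling nuclei, and 0.0514 and 0.0656 at 6 and 24 h with leading genes ranked by fold over all other nuclei. For microglia-like nuclei they were 0.0223, 0.596 and 0.718 at 6, 24 and 72 h with the order-of-magnitude rule, 0.00252 and 0.0225 at 6 and 24 h at a resolution of 0.5, 0.00338 and 0.0255 with the other ranking, and at 6 h 0.0749 with each library clustered alone and 0.662 with cluster 29 counted as microglia. In the other classes, clustering alone gave inhibitory ratios of 1.49 and 1.28 at 24 and 72 h, a D2 ratio of 0.877 at 6 h and a macrophage ratio of 0.510 at 72 h, and the other ranking gave at 24 h an inhibitory ratio of 1.45, a D1 ratio of 0.611, a D2 ratio of 0.579, an astrocyte ratio of 2.02, a T or NK cell ratio of 1.12 and a precursor ratio of 0.940. The order-of-magnitude rule gave astrocyte ratios of 4.11 and 0.831 at 6 and 24 h and a neuroblast ratio of 0.883 at 6 h, and a resolution of 2.0 an inhibitory ratio of 0.881 at 6 h. The macrophage ratio at 24 h, on 9 nuclei, was 0.0368, against 0.127 with each library clustered alone, 0.0674 with a floor of 1000 genes, 0.0656 with doublets kept and 0.0241 with at most 1% mitochondrial UMIs.

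**Figure D1:**
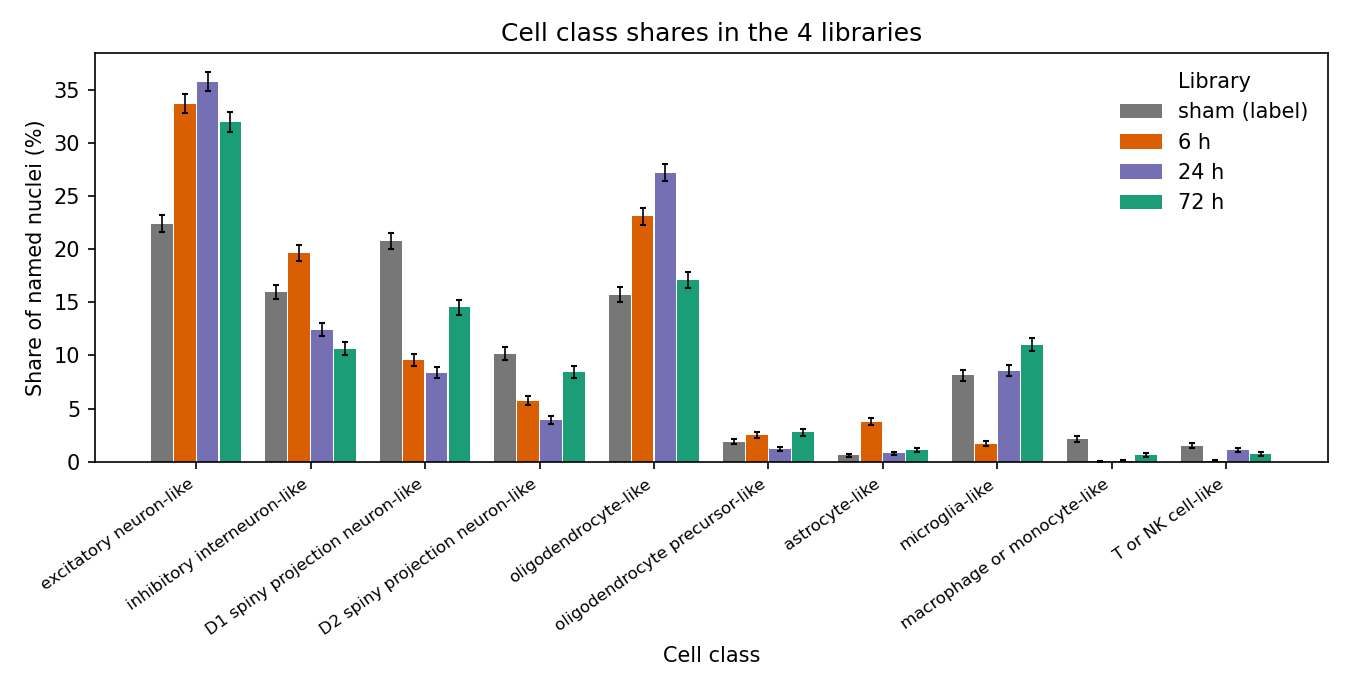
Share of named nuclei (%) of 10 cell classes in the 4 libraries, 1 library per group, with exact 95% intervals that cover counting error only. Microglia-like nuclei make up 1.68% at 6 h against 8.13% in the library labelled sham, and oligodendrocyte-like nuclei 27.2% at 24 h against 15.7%. The microglia ratio of 0.207 at 6 h is 0.662 with the unnamed cluster 29 counted as microglia.

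At 6 h, microglia-like nuclei held more transcripts of cytokines and of the antioxidant response than in the library labelled sham, and fewer of cell division. Astrocyte-like nuclei held more interferon and chemokine transcripts. Oligodendrocyte-like nuclei held more transcripts of glucocorticoid-induced and interferon-induced genes, and their precursors more of glucocorticoid-induced genes. Excitatory and D1-type neuron-like nuclei held fewer immediate early transcripts, the genes switched on within minutes of neuronal activity, when compared with sham, but not when compared with 72 h. In inhibitory neuron-like nuclei the median against sham turned to 0.90 with the second free RNA profile.

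Of 24 measured cytokine and chemokine genes in the 179 microglia-like nuclei, 21 were over 1.5-fold higher at 6 h and 0 over 1.5-fold lower, a median log2 ratio of 2.35 (2.21 to 2.81) above all 10000 random lists of like expression. Ccl4, a chemokine that draws in leukocytes, stood at 858 CPM against 11.6, 74.3-fold higher (52.9 to 107). Tnf, a central inflammatory cytokine, stood at 641 CPM against 13.1, 48.9-fold higher (35.3 to 69.2). Il12b, a subunit of cytokines that activate T cells, had 272 UMIs against 0, at least 644-fold higher, and Il6 had 60 against 0, at least 142-fold higher. Tnf had a UMI in 34.6% (27.7 to 42.1) of thinned microglia-like nuclei at 6 h, against 1.12% in the library labelled sham, 8.89% at 24 h and 0.568% at 72 h. The unthinned shares were 50.8%, 3.93%, 19.4% and 2.65% in that order, and the thinned shares in excitatory neuron-like nuclei 0.0837%, 0, 0.0476% and 0. Of 16 NRF2 antioxidant genes, 14 were over 1.5-fold higher and 1 lower, a median of 2.55 (2.31 to 3.01). Slc7a11, which imports cystine for glutathione, was 111-fold higher (89.3 to 139), Hmox1, which degrades heme, 20.2-fold (16.4 to 25.14) and Gclm, of glutathione synthesis, 11.4-fold (7.95 to 16.5).

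Homeostatic microglia genes, which mark the resting state, had a median of -0.79 (-0.94 to -0.67) at 6 h, with 11 of 18 over 1.5-fold lower and 1, Cst3, higher. The receptor gene Gpr34 was 6.23-fold lower (3.25 to 13.7), Olfml3 4.49-fold (2.65 to 8.27) and Bin1 3.58-fold (2.88 to 4.50), while the protease inhibitor gene Cst3 was 6.14-fold higher (5.74 to 6.58). Cell cycle genes had a median of -3.94 (-4.50 to -3.74), with 25 of 26 over 1.5-fold lower, and -3.15 with the 17 members under 3 UMIs set at their bound. Mki67, a mark of dividing cells, had 0 UMIs against 421, at least 19.8-fold lower, and Top2a 1 against 614, 86.5-fold lower (15.5 to 3421). Interferon genes of microglia-like nuclei had a median of 0.10 (-0.17 to 0.25).

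In 399 astrocyte-like nuclei at 6 h against 63, 21 of 22 interferon response genes were over 1.5-fold higher and 0 lower, a median of 3.70 (3.405 to 4.33), or 3.54 with 6 members at their bound. Rsad2, an antiviral enzyme, was 36.2-fold higher (15.5 to 112), and Ifit1 had 447 UMIs against 2, a ratio of 41.3 (11.4 to 342). All 16 measured cytokine genes were over 1.5-fold higher, with a median of 3.63 (3.32 to 3.97), or 1.95 with the 11 members under 3 UMIs at their bound. Cxcl10, a chemokine that attracts T cells, stood at 2579.9 CPM against 10.4, a ratio of 248 (84.7 to 1201) on 3 sham UMIs. The A1 panel, defined in inflammation, had a median of 2.68 (2.37 to 3.97) over 10 genes, or 2.37 at the bounds, and the A2 panel, defined in ischemia, 1.999 (1.47 to 3.34) over 8 genes, or 1.56. Among them, the GTPase gene Iigp1 had 1094 UMIs against 1, a ratio of 202 (36.2 to 7990.3), and Gbp2 a ratio of 87.7 (24.2 to 725) on 2 sham UMIs. Fkbp5, a glucocorticoid-induced gene, was 25.0-fold higher (13.1 to 54.9), and Ptx3 4.28-fold (2.41 to 8.38). The amino acid transporter gene Slc38a1 was 16.0-fold lower (9.34 to 28.4).

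Glucocorticoid response genes of oligodendrocyte-like nuclei had a median of 2.47 (2.33 to 2.62) at 6 h, with 17 of 20 over 1.5-fold higher and 1 lower. The lipid droplet gene Plin4 was 49.8-fold higher (32.7 to 79.6), Hif3a 36.9-fold (23.2 to 62.6) and the metallothionein gene Mt1 36.5-fold (29.4 to 45.8). Interferon response genes had a median of 2.34 (2.13 to 2.63), with 20 of 21 higher and 0 lower, including Rsad2 at 46.7-fold (19.8 to 145) and Usp18, which restrains interferon signaling, at 13.6-fold (8.86 to 21.9). The cell cycle inhibitor gene Cdkn1a was 79.3-fold higher (41.6 to 174), with a UMI in 12.3% of thinned nuclei against 0.174% in the library labelled sham, where excitatory neuron-like nuclei gave 0.285%. At 24 and 72 h the thinned Cdkn1a shares were 7.62% and 0.244%, against 0.262% and 0.0978% in those neurons, and the unthinned shares 0.522%, 30.3%, 19.7% and 1.28% from sham to 72 h. Median depths of oligodendrocyte-like nuclei were 2898, 2856, 2713 and 3762 UMIs, and 0, 6, 10 and 0 were too shallow to thin. Mrgpra1 had 283 UMIs against 1, a ratio of 207 (36.9 to 8207), and the collagen gene Col2a1 was 24.8-fold lower (12.2 to 58.5). Immediate early genes were higher in 15 of 22 and lower in 6, a median of 1.52 (1.17 to 1.66), with Btg2 7.01-fold higher (5.11 to 9.84). Complement and MHC genes had a median of -2.46 (-2.64 to -1.71), with 13 of 17 lower, among them Itgam at 14.8-fold (6.45 to 41.8). The estimated share of free RNA in these nuclei was 24.0% in the library labelled sham and 11.8% at 6 h.

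In oligodendrocyte precursor-like nuclei at 6 h, 13 of 14 glucocorticoid response genes were higher, a median of 2.43 (2.21 to 2.96), with Mt1 at 36.8-fold (18.5 to 85.7) and the transcription factor gene Cebpd at 22.3-fold (9.38 to 69.7). Hypoxia and glycolysis genes had a median of 0.83 (0.54 to 1.14), with 11 of 18 higher, among them Vegfa, which drives vessel growth, at 3.84-fold (2.99 to 4.98), and Pdk1 at 4.89-fold (2.59 to 10.2). The chemokine gene Ccl2 was 311-fold higher (121 to 1144), Cxcl10 had 1419 UMIs against 2, a ratio of 483 (133 to 3992), and the ion channel gene Piezo2 was 11.3-fold lower (5.601 to 25.7). Ccl2 and Cxcl10 were leading genes of cluster 18.5, with 67 nuclei at 6 h and 0 in sham, which had no precursor marker among its leading genes. Ccl2 was also a leading gene of cluster 18.7, with 58 nuclei at 6 h and 0 in sham.

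Immediate early genes of excitatory neuron-like nuclei had a median of -1.13 (-1.18 to -1.06) at 6 h, with 16 of 23 over 1.5-fold lower and 1 higher, but of 0.34 when the 72 h library was the baseline. The nuclear receptor gene Nr4a3 was 9.64-fold lower than sham (8.33 to 11.2), Egr2 4.41-fold (3.13 to 6.33) and Egr3 2.91-fold (2.64 to 3.21). D1-type nuclei had a median of -1.28 (-1.48 to -0.95) against sham and 0.14 against 72 h. In D1-type nuclei Trhr, a hormone receptor gene, was 12.1-fold lower (6.25 to 26.8). In D2-type nuclei Robo3 was 12.8-fold higher (10.1 to 16.4) and Trhr 30.5-fold lower (11.7 to 113). D2-type nuclei numbered 597 and 517 in clusters 7 and 15 in sham against 511 and 97 at 6 h. D1-type nuclei numbered 822, 851, 366 and 234 in clusters 3, 11, 20 and 26 against 803, 136, 44 and 37. Within matched clusters, Robo3 was 8.43 and Trhr 0.0558 times its sham level in D2-type nuclei. In inhibitory interneuron-like nuclei Oxt, the hormone oxytocin of hypothalamic neurons, had 2162 UMIs against 3, a ratio of 669.7 (229 to 3249.95), and Ifi203, an interferon-induced gene, was 18.1-fold higher (8.08 to 50.4). These nuclei also lay in different clusters, among them 4, 23 and 41 with 709, 321 and 1 nuclei in sham against 1269, 16 and 64 at 6 h. The Oxt ratio may thus reflect which neurons each library held. In excitatory neuron-like nuclei Lef1 was 65.9-fold higher (36.7 to 132) and Ndst4 32.1-fold lower (28.2 to 36.7).

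Within clusters matched between the libraries, Lef1 at 6 h was 0.504 times its level in sham and Ndst4 0.194 times. Mrvi1 was 1.18 times its sham level there, against 40.4 (15.6 to 150) over all excitatory neuron-like nuclei. The rise of Lef1 and nearly all of that of Mrvi1 thus lay in which neurons each library held, as did part of the fall of Ndst4. Lef1 was a leading gene of cluster 28, with 352 nuclei at 6 h and 0 in sham. Under other settings any count under 3 UMIs was set to 3, so values on such counts are bounds. After thinning, Il12b is thus at least 139 and Il6 at least 49.7. Of 833 single-gene folds at 6 h under other settings, 210 moved by over 1.5-fold, and among the settings that turned or moved values given here by as much were clustering each library alone (Ccl4 30.5, Tnf 18.8, Il6 75.3, Gpr34 0.390, Rsad2 in oligodendrocytes 20.5, Oxt 10.4, cytokines in microglia 1.65, NRF2 1.79, cell cycle -2.81), 5 added counts (cytokines in astrocytes 1.40, interferon in astrocytes 2.81, A1 1.56, A2 0.67, cell cycle -1.95), counting cluster 29 as microglia (Ccl4 389, Tnf 105, cytokines 4.28, homeostatic -1.73), keeping doublets (NRF2 1.62, Gclm 6.05, Hmox1 11.7, Fkbp5 14.0, Slc38a1 0.175, Cebpd 10.1, Pdk1 2.78, Robo3 6.77), no minimum count (cytokines in astrocytes 2.11), thinning (A1 4.13, Il12b 139, Il6 49.7, Cxcl10 in astrocytes 60.9, Rsad2 in astrocytes 10.5, Mrgpra1 18.8, Ccl2 69.7, Cebpd 7.02, Trhr 0.373 in D1-type and 0.393 in D2-type nuclei, Oxt 28.8, Ifi203 1.68, Lef1 13.02, complement and MHC in oligodendrocytes -1.83), subtraction of free RNA (complement and MHC in oligodendrocytes -1.46 and -1.53, immediate early genes in oligodendrocytes 3.44 and 3.87, glucocorticoid genes in precursors 3.46, hypoxia 1.52) and the 72 h baseline (Plin4 3.11, Hif3a 2.92, Cst3 1.15, Egr2 1.66 and Btg2 1.27 in excitatory neurons, cytokines in microglia 3.63 and in astrocytes 4.43, homeostatic -1.75, cell cycle -2.88, interferon in oligodendrocytes 3.48, glucocorticoid in oligodendrocytes 1.37, complement and MHC in oligodendrocytes -1.42, A2 2.94, immediate early genes in oligodendrocytes 2.34).

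At 24 h, cytokine transcripts of microglia-like nuclei were higher than in the library labelled sham, and cell cycle transcripts were again lower. Astrocyte-like nuclei held more transcripts of reactive astrocytes, of iron handling and of cholesterol synthesis. Oligodendrocyte-like nuclei held more interferon and glucocorticoid transcripts and less of several myelin transcripts.

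Of 24 cytokine genes in 1002 microglia-like nuclei, 18 were over 1.5-fold higher and 0 lower, a median of 1.62 (1.42 to 1.80). Ccl4 was 45.3-fold higher (32.7 to 64.5), Ccl3 21.1-fold (16.6 to 27.3) and Il1rn, which blocks interleukin signaling, 26.0-fold (9.86 to 97.2). NRF2 genes had a median of 0.99 (0.79 to 1.36), with 9 of 16 higher and 1 lower, led by Slc7a11 at 13.1-fold (10.5 to 16.4), with the mitochondrial enzyme gene Sod2 at 6.27-fold (5.23 to 7.58). Hif3a was 26.6-fold higher (11.1 to 83.3). Homeostatic genes had a median of -0.33 (-0.39 to -0.28) and interferon genes -0.84 (-0.99 to -0.71). Cell cycle genes had a median of -4.37 (-4.67 to -4.03), with 24 of 27 lower, or -4.24 with 5 members at their bound. Mki67 had 6 UMIs against 421, 72.2-fold lower (32.9 to 198), Kif11, a motor protein of the spindle, was 70.2-fold lower (29.8 to 217), and the noncoding RNA gene Lockd had 0 against 306, at least 105-fold lower.

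In 90 astrocyte-like nuclei at 24 h, all 16 measured pan-reactive genes were over 1.5-fold higher, a median of 2.05 (1.70 to 2.30). Among them, Serpina3n, a protease inhibitor gene, stood at 6.41-fold (4.28 to 9.95) and Cxcl10 at 46.6-fold (15.7 to 228) on 3 sham UMIs. Gfap, the intermediate filament of astrocytes, had a UMI in 41.1% (30.8 to 52.0) of thinned nuclei, against 9.52% in the library labelled sham, 35.8% at 6 h and 8.82% at 72 h. The unthinned Gfap shares were 82.2%, 34.9%, 70.9% and 25.5% in that order, the thinned shares in excitatory neuron-like nuclei 0.119%, 0.122%, 0.0279% and 0.0978%, and the median depths of astrocyte-like nuclei 3741.5, 4204, 3668 and 5824 UMIs. Ptx3, which binds microbes and debris, was 56.2-fold higher (32.0 to 109). Iron and heme handling genes had a median of 1.23 (1.01 to 1.66), with 7 of 10 higher and 0 lower. Among them were the zinc and iron importer gene Slc39a14 at 4.54-fold (3.00 to 7.12) and the ferritin gene Fth1 at 4.33-fold (2.79 to 7.01). Hmox1 had 61 UMIs against 1, a ratio of 49.6 (8.57 to 1989). Ribosomal protein genes, read as a sign of cytoplasmic RNA, had a median of 1.07 (0.42 to 1.33) in the same nuclei. Cholesterol synthesis genes had a median of 1.61 (1.28 to 2.27), with 9 of 11 higher and 1 lower, including Sqle at 7.31-fold (2.62 to 28.3) and Cyp51 at 4.65-fold (2.43 to 9.79). Diaph3, a gene of cytokinesis, was 5.02-fold lower (2.70 to 10.0).

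In 3197 oligodendrocyte-like nuclei at 24 h, 21 of 22 interferon response genes were higher and 0 lower, a median of 2.26 (2.003 to 2.46), with Ifit3 at 41.4-fold (20.9 to 96.4) and Oasl2 at 11.9-fold (8.67 to 16.8). Glucocorticoid response genes had a median of 2.19 (2.07 to 2.37), with 18 of 20 higher and 2 lower, among them Plin4 at 40.7-fold (26.8 to 65.2) and Fkbp5 at 10.9-fold (9.67 to 12.3). Reactive oligodendrocyte genes had a median of 0.61 (0.51 to 0.96), with 10 of 20 higher and 1 lower, including Cdkn1a at 51.1-fold (26.8 to 112) and Cd63, of late endosomes, at 4.94-fold (4.56 to 5.35). Myelin genes had a median of -0.30 (-0.33 to -0.28), with 6 of 19 lower and 3 higher. Mbp, a major myelin protein, was 2.05-fold lower (2.003 to 2.10), Ugt8a, of myelin lipid synthesis, 2.38-fold (2.28 to 2.47) and Opalin 2.18-fold (2.02 to 2.35), while Hapln2, a matrix gene of the node of Ranvier, was 3.99-fold higher (3.70 to 4.31). Ribosomal protein genes had a median of 0.78 (0.72 to 0.85), and Eef1a1 was 2.39-fold higher (2.18 to 2.63). Fga, a fibrinogen chain, had 413 UMIs against 0, at least 82.0-fold higher.

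In oligodendrocyte precursor-like nuclei Hmga2, a chromatin gene, had 344 UMIs against 0, at least 156-fold higher, and the protease gene Adamts1 was 44.0-fold higher (16.8 to 164). T or NK cell-like nuclei held 5.45-fold more Gzma (3.10 to 10.1), a killing protease, and 0 UMIs of Igkc against 60, at least 13.8-fold lower. Neuroblast-like nuclei held 4.22-fold more Igfbpl1 (3.14 to 5.77). Immediate early genes of excitatory neuron-like nuclei had a median of -0.69 (-0.85 to -0.62) against sham, with 14 of 23 lower and 2 higher, and 0.52 against 72 h. Nr4a3 was 7.18-fold lower than sham (6.38 to 8.09), Fosb 3.27-fold (2.66 to 4.04) and Egr2 5.09-fold (3.65 to 7.21), and against 72 h Fosb and Egr2 were 1.62 and 1.44 times as high. Inhibitory interneuron-like nuclei held 15.3-fold more Avp (11.2 to 21.3), the hormone vasopressin, and 22.1-fold less of the collagen gene Col6a3 (13.5 to 39.0). Clusters 4, 23 and 41 of this class had 709, 321 and 1 nuclei in sham against 439, 76 and 73 at 24 h. The Avp ratio may thus reflect which neurons each library held. D1-type and D2-type nuclei held 3.57-fold (2.72 to 4.70) and 4.37-fold (3.02 to 6.38) more Dmkn.

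Of 773 single-gene folds at 24 h under other settings, 145 moved by over 1.5-fold, and among the settings that turned or moved values given here by as much were clustering each library alone (Il1rn 6.70, Cdkn1a 32.0, Avp 123, Col6a3 0.0274), a floor of 1000 genes (Il1rn 11.98, Gzma 3.08), keeping doublets (Mki67 0.0418, Kif11 0.0233, Hif3a in microglia 15.9, Sod2 3.31, Sqle 4.02, Diaph3 0.3004, Cdkn1a 30.4, Hmga2 76.0, Adamts1 25.3), thinning (Il1rn 14.2, Hif3a in microglia 10.97, Kif11 0.0556, Lockd 0.0545, Cxcl10 11.4, Hmox1 3.97, Sqle 2.80, Slc39a14 10.0, Ifit3 20.1, Fga 20.7, Hmga2 30.1, Adamts1 13.03), subtraction of free RNA by the planned profile (Fosb 0.817, Egr2 0.510, Nr4a3 0.285, Sod2 12.5, NRF2 in microglia 1.66, Avp 236) and by the other (Fth1 8.98, Cdkn1a 98.6, Ifit3 70.7), matched clusters (Col6a3 0.0838) and 5 added counts (cell cycle -3.57). Fga, Hmga2 and Lockd had no UMIs in the lower library, so their thinned values are bounds: at least 20.7, at least 30.1 and at most 0.0545. With the 72 h library as the baseline, medians were 2.60 for cytokines and -3.29 for the cell cycle in microglia, 3.45 for pan-reactive and 0.57 for iron genes in astrocytes, and 3.11 for interferon and 1.29 for glucocorticoid genes in oligodendrocytes, and folds were 2.55 for Plin4 and 3.17 for Hif3a in oligodendrocytes and 1.02 for Egr3 in excitatory neurons.

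**Figure D2:**
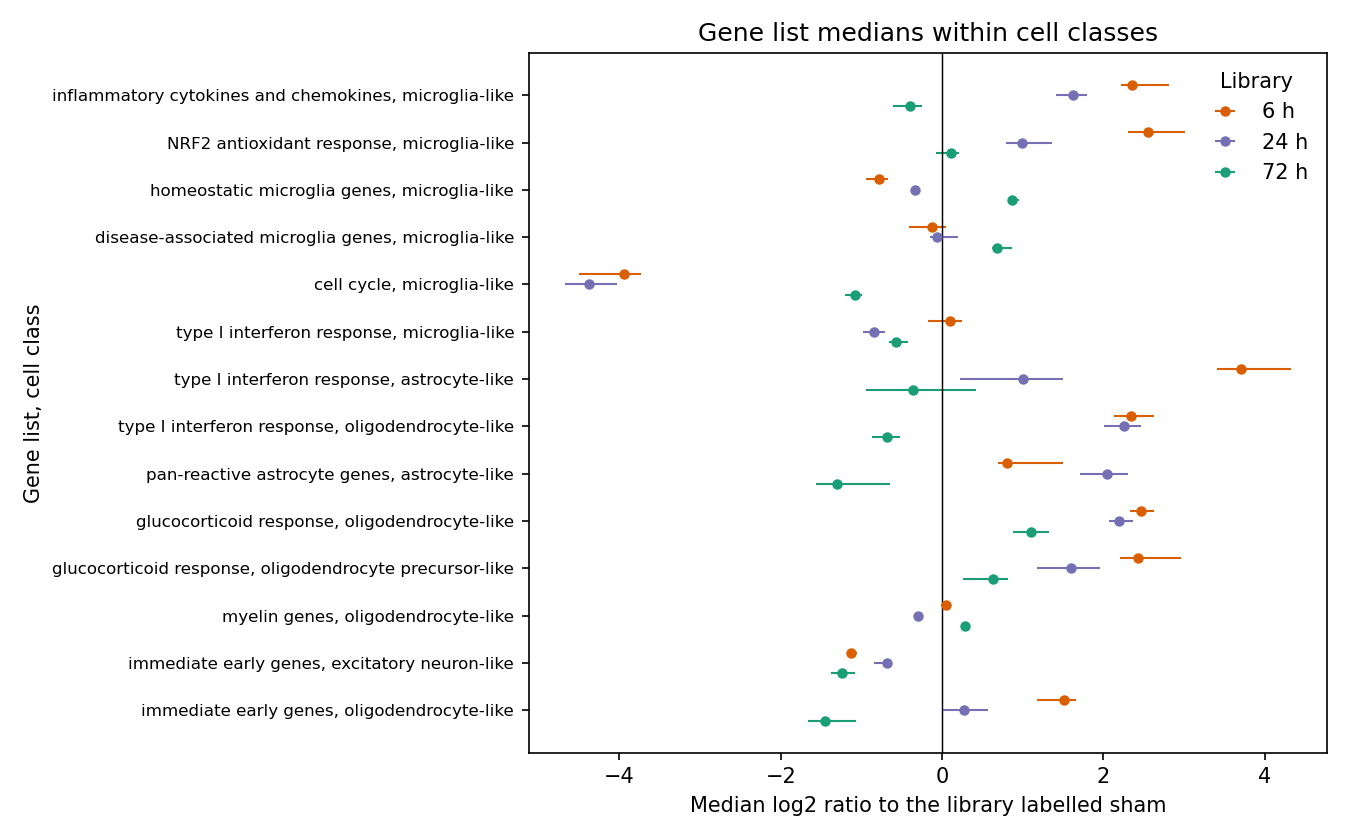
Median log2 ratio to the library labelled sham for 14 pairs of gene list and cell class at 6, 24 and 72 h, with 95% intervals from redrawn counts that cover counting error only. Interferon genes of oligodendrocyte-like nuclei stand at 2.34 and 2.26 at 6 and 24 h and at -0.68 at 72 h.

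At 72 h, microglia-like nuclei held more homeostatic and disease-associated microglia transcripts than in the library labelled sham and fewer cell cycle and interferon transcripts. Macrophage-like nuclei held more transcripts of disease-associated microglia genes and of antigen presentation, and more of some iron handling genes. The size of the antigen presentation difference depended on how clusters were split and named. Oligodendrocyte-like nuclei held slightly more myelin transcripts and fewer interferon transcripts, and excitatory and D1-type neuron-like nuclei fewer immediate early transcripts.

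Of 18 homeostatic genes in 1058 microglia-like nuclei, 15 were over 1.5-fold higher and 0 lower, a median of 0.87 (0.84 to 0.96). Cst3 was 5.34-fold higher (5.08 to 5.61), the fructose transporter gene Slc2a5 5.02-fold (3.79 to 6.77) and Gpr34 4.16-fold (3.74 to 4.63). Disease-associated microglia genes, named for microglia around amyloid plaques, had a median of 0.69 (0.62 to 0.86), with 16 of 23 higher and 0 lower. Among them were the growth factor gene Igf1 at 3.27-fold (1.98 to 5.70) and the lysosomal gene Cd68 at 2.46-fold (2.11 to 2.87). Gpnmb was 4.09-fold higher (1.99 to 9.43). Cell cycle genes had a median of -1.08 (-1.21 to -0.99), with 25 of 28 lower, including Hells at 2.93-fold (2.28 to 3.79) and Mki67 at 2.73-fold (2.31 to 3.23). Interferon genes had a median of -0.58 (-0.66 to -0.43), with 11 of 22 lower, such as Ifit2 at 0.446 times its sham level (0.315 to 0.626). Slc13a3, a transporter gene, was 10.4-fold lower (8.20 to 13.5), and the heat shock gene Hspa1a had 57 UMIs against 2, a ratio of 20.2 (5.33 to 170).

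The 59 macrophage-like nuclei at 72 h lay mostly in clusters 25.5, 25.2 and 25.8, and the 228 of sham mostly in 25.0 and 25.2. Iron and heme handling genes had a median of 0.59 (0.35 to 0.85), with 10 of 19 higher and 4 lower. The iron exporter gene Slc40a1 was 33.7-fold higher (13.6 to 108), the hemoglobin scavenger receptor gene Cd163 7.51-fold (3.94 to 15.1) and the heme pathway gene Blvrb 3.31-fold (2.10 to 5.25), while the importer gene Slc39a14, with 4 UMIs, was 8.90-fold lower (3.38 to 33.3). Disease-associated microglia genes had a median of 1.15 (1.01 to 1.38), with 15 of 19 higher and 0 lower, among them the lipid scavenger gene Cd36 at 10.7-fold (5.35 to 23.1) and Spp1 at 8.15-fold (6.15 to 10.9). Complement and MHC genes had a median of 1.03 (0.88 to 1.20), with 13 of 18 higher and 2 lower, including Cd74, the MHC class II chaperone, at 10.5-fold (7.78 to 14.4) and H2-Ab1 at 6.98-fold (5.11 to 9.64). Clec4e, a receptor for dead cells and microbes, had 1 UMI against 89, 29.6-fold lower (5.18 to 1183).

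Myelin genes of 1642 oligodendrocyte-like nuclei at 72 h had a median of 0.28 (0.23 to 0.34), with 7 of 19 higher and 0 lower, such as Mal at 2.08-fold (2.01 to 2.15). Glucocorticoid response genes had a median of 1.10 (0.88 to 1.33), with 13 of 19 higher and 2 lower, among them Plin4 at 16.0-fold (10.4 to 25.8) and the kinase gene Sgk1 at 5.14-fold (4.74 to 5.58). Interferon genes had a median of -0.68 (-0.87 to -0.52), with 11 of 17 lower and 1 higher, including Irf1 at 0.219 times its sham level (0.112 to 0.401). Precursor-like nuclei held 5.42-fold more Enpp6 (2.99 to 10.8), a mark of newly forming oligodendrocytes, with 62 and 44 nuclei in clusters 18.4 and 18.6 against 5 and 11 in sham. They also held 4.22-fold more Bmp4 (2.45 to 7.80) but 5.96-fold less Top2a (3.52 to 10.5), which after thinning stood at 0.390 times its sham level. Pan-reactive genes of 102 astrocyte-like nuclei had a median of -1.30 (-1.57 to -0.64), with 7 of 11 lower and 1 higher. Cp, the ferroxidase ceruloplasmin, was 25.5-fold lower (10.3 to 81.5), and Cxcl10 9.40-fold higher (3.07 to 46.9) on 3 sham UMIs. The receptor gene Ror1 was 27.0-fold lower (9.92 to 103).

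Immediate early genes had a median of -1.24 (-1.37 to -1.08) in excitatory neuron-like nuclei at 72 h, with 17 of 23 lower and 0 higher, and -1.37 (-1.59 to -1.21) in D1-type nuclei, with 19 of 22 lower. In D1-type nuclei Egr2 was 6.80-fold lower (3.80 to 13.2) and Fos 5.32-fold (3.57 to 8.18). Ifit1 was 12.7-fold lower (6.25 to 30.2) in D1-type nuclei, Macc1 3.51-fold higher (2.32 to 5.50) in excitatory neuron-like nuclei and Cox6a2 4.34-fold higher (2.93 to 6.59) in inhibitory interneuron-like nuclei. The transcription factor gene Sim1 had 0 UMIs against 139 in inhibitory interneuron-like nuclei, at least 33.3-fold lower. It stood at 0.782 times sham with each library clustered alone and at most 0.0177 in matched clusters, so it depended on which neurons the class held. T or NK cell-like nuclei held 3.33-fold more Cd52 (2.13 to 5.27) and 0 UMIs of Igkc against 60, at least 9.54-fold lower, where free RNA as the source of Igkc was again not tested.

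Of 746 single-gene folds at 72 h under other settings, 94 moved by over 1.5-fold, and among the settings that turned or moved values given here by as much were clustering each library alone (disease-associated genes in macrophages 1.74, complement and MHC in macrophages 2.09, Cd74 44.0, H2-Ab1 42.2, Slc40a1 9.84, Cd163 23.9, Spp1 4.89, Cox6a2 2.51, Bmp4 2.66, Sim1 0.782, Cxcl10 in astrocytes 0.484), keeping doublets (pan-reactive -0.44, Enpp6 2.12, Cd74 2.57, H2-Ab1 2.09, Ror1 0.316, Cp 0.0973, Hspa1a 8.33, Gpnmb 0.585, Cxcl10 in astrocytes 0.452), no second clustering (Cd74 3.10, H2-Ab1 2.31, Enpp6 2.40, Slc40a1 8.70), thinning (Enpp6 2.86, Slc40a1 10.3, Cd163 11.6, Slc39a14 0.330, Clec4e 0.413, Ror1 0.464, Cp 0.185, Hspa1a 3.65, Gpnmb 1.97, Macc1 1.33, Cox6a2 2.85, Sim1 0.570, Egr2 and Ifit1 in D1-type nuclei 0.610 each), matched clusters (Cox6a2 2.30) and subtraction of free RNA (Fos in D1-type nuclei 6.71, Cox6a2 12.9, immediate early genes in oligodendrocytes 0.35 against -1.45). Any count under 3 UMIs was set to 3 in these values, so those on such counts are bounds: after thinning, Sim1 is at most 0.570 and Clec4e at most 0.413. Moves were judged from main values set in the same way, 13.4 for Hspa1a in microglia and 0.101 for Clec4e. Scaling by the median of gene ratios shifted all genes, on the log2 scale, by -0.21 in excitatory, -0.12 in inhibitory, -0.10 in D1-type, -0.19 in microglia-like, 0.12 in precursor-like and 0.26 in astrocyte-like nuclei at 6 h, by -0.14 in excitatory and 0.13 in astrocyte-like nuclei at 24 h, and by 0.17 in astrocyte-like and -0.16 in T or NK cell-like nuclei at 72 h.

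**Figure D3:**
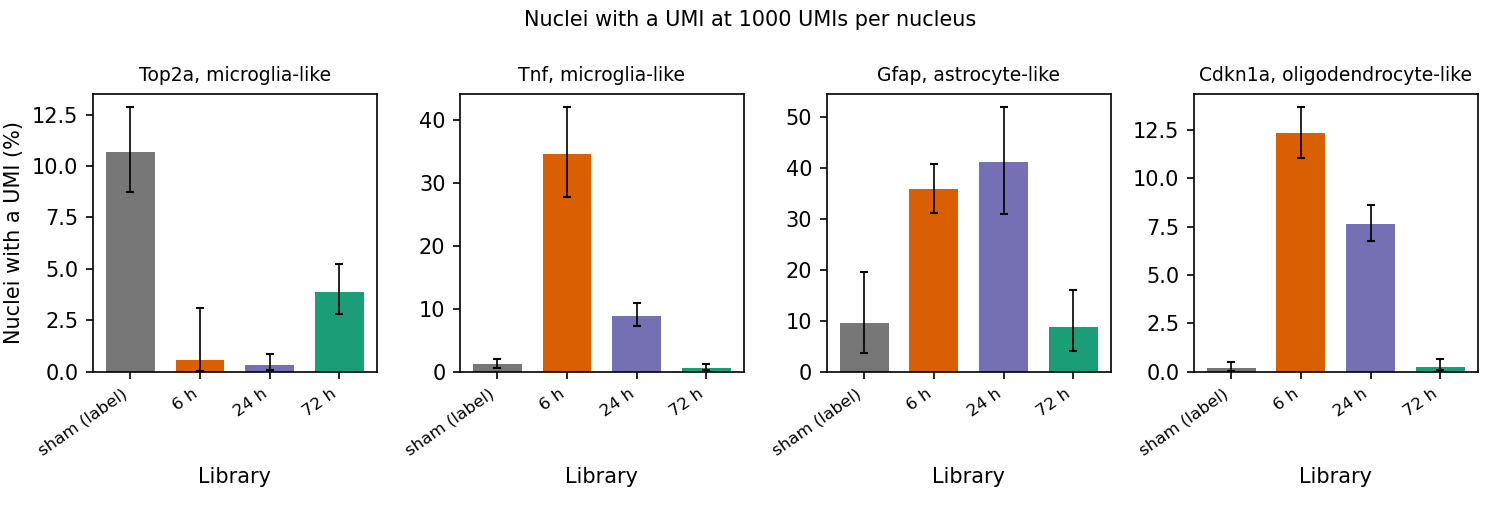
Share of nuclei (%) with at least 1 UMI of Top2a and Tnf in microglia-like, Gfap in astrocyte-like and Cdkn1a in oligodendrocyte-like nuclei, each nucleus thinned to 1000 UMIs, with exact 95% intervals that cover counting error only. Tnf is found in 34.6% of microglia-like nuclei at 6 h against 1.12% in the library labelled sham, and Gfap in 41.1% of astrocyte-like nuclei at 24 h against 9.52%.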

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

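Of the tests in this part, those of mixing, of exchanged labels, of regions and of small cells were chosen only after the result was seen, as were the empty droplets of over 200 UMIs and under 600 genes and the size that opposite directions had to reach.

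Empty droplets, outside the nuclei compared, held hemoglobin transcripts at 504 CPM at 6 h and 123 CPM at 24 h, above 1.25 CPM in the library labelled sham, and at 1.88 CPM at 72 h. In the empty droplets of 10 to 100 UMIs, the range planned, the same sum was 61.5 CPM at 6 h, on 18 UMIs, and 0 in the other libraries. S100a8, a neutrophil gene, stood in the larger set at 50.1 CPM at 24 h, above 4.31 in the library labelled sham, 2.93 at 6 h and 0.758 at 72 h, but in the planned range it had 1 UMI in sham and 0 at 24 h (at most 16.95 CPM).

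Some list medians lay on opposite sides of sham at different times, and these differences were not tested. Immediate early genes stood at 1.12 at 6 h and -0.62 at 72 h in microglia-like nuclei. In oligodendrocyte-like nuclei they stood at 1.52 at 6 h and -1.45 at 72 h, where the second free RNA profile turned the value to 0.35. Interferon response genes of oligodendrocyte-like nuclei stood at 2.34 and 2.26 at 6 and 24 h and at -0.68 at 72 h. Homeostatic genes of microglia-like nuclei stood at -0.79 at 6 h and 0.87 at 72 h. Pan-reactive genes of astrocyte-like nuclei stood at 0.80 and 2.05 at 6 and 24 h and at -1.30 at 72 h.

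The library labelled sham held macrophage-like, T or NK cell-like and dividing microglia-like nuclei at higher shares than any other library, except that with leading genes ranked by fold over all other nuclei the T or NK cell-like ratio of 24 h to sham was 1.12. As the source of the macrophage-like nuclei alone, mixing with another library of the series was argued against, since a mixture cannot hold a higher share than its richest source and the richest other library held 0.614% (0.468 to 0.791) macrophage-like nuclei against 2.08%, and so was barcode hopping, since 5 of 392 macrophage-like and T or NK cell-like barcodes, 1.28% (0.415 to 2.95), were also nuclei in another library, near the 1.02% of all its barcodes. An exchange of labels with the 72 h library was judged first on iron genes in macrophage-like nuclei, which stood 0.59 (0.35 to 0.85) higher in the 72 h library, on 59 nuclei there, and this goes against an exchange by the bound set. A second judgment, added after that result and with all its values known, took 6 readouts, of which 4 stood higher in the library labelled sham (72 h over sham: macrophage-like share 0.295, T or NK cell-like share 0.452, cell cycle in microglia -1.08, pan-reactive genes in astrocytes -1.30) and the other 2, disease-associated genes in microglia (0.69) and the iron genes, did not. An exchange with the 72 h library, a sample from outside the series and tissue injury by the sham procedure itself cannot be told apart, as both judgments came after the values and each group has 1 library.

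Interferon response genes stood higher at 6 and 24 h than in sham in oligodendrocyte-like nuclei, and also higher than at 72 h (3.48 and 3.11). Free RNA alone was argued against, since the list stood at 1.87 and 3.79 times its level in the empty droplets at 6 and 24 h, against 1.68 in sham and 1.84 at 72 h. The list summed to 407, 1821, 1468 and 312 CPM in oligodendrocyte-like nuclei from sham to 72 h, to 242, 975, 387 and 169.99 CPM in empty droplets and to 127, 395, 166 and 122 CPM in excitatory neuron-like nuclei. Doublets with astrocytes or microglia were argued against, since nuclei without a UMI of their markers kept medians of 2.30 (1.99 to 2.65) and 2.32 (1.83 to 2.47), on 1400 and 1545 nuclei against 547 in sham. A response to hemorrhage may be the cause, as a hypothesis from the same data, while differences between animals or between library preparations were not tested and stay open.

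Spiny projection neuron-like nuclei held lower shares at 6 and 24 h than in sham. More nuclei of small cells were argued against as the whole cause, since among neuron-like nuclei alone the D1 share was 0.467 and 0.462 times that of sham. The libraries held different neuron clusters: cluster 28 had 352 nuclei at 6 h, 75 at 24 h and 0 in sham and at 72 h. Clusters 16 and 37 had 237 and 53 nuclei in sham and 0 at 6 h. How far tissue pieces from different regions account for the lower shares stays open. Clusters that hold under 1% of the sham neuron-like nuclei, 12 of 32, held 12.2% of those at 6 h and 10.3% at 24 h, 6.79% at 72 h and 3.87% in sham, and the reverse shares, of sham in clusters rare at 6, 24 and 72 h, were 18.7%, 2.23% and 2.86%. A first form of this test with fixed bounds favored one answer by its construction and was replaced after its values were seen. D1-type clusters 3, 11, 20 and 26 had 822, 851, 366 and 234 nuclei in sham. They had 803, 136, 44 and 37 at 6 h and 431, 322, 130 and 100 at 24 h. The lower D1 count at 6 h thus lay in some clusters and hardly in cluster 3, while at 24 h it lay in all of these. Loss of these neurons after hemorrhage and a difference in the piece of tissue taken cannot be told apart here, since either could fall on some clusters more than on others.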

How the results depend on the processing

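Settings added after seeing the data were cluster 29 counted as microglia, no second clustering, the other ranking of leading genes, the 72 h baseline, matched neuron clusters and the second free RNA profile; no test was made in this part. No paired analysis was possible because each group had 1 library. Depth limits folds that rest on few UMIs: after thinning 8 folds, and after subtraction of free RNA 1 fold, gave no bound, by a rule set after values were seen. Class shares under the floor of 300 genes were not run, and the shares with a floor of 1000 kept the doublets of the floor used. A turn was counted only for results whose interval excluded no difference and, for lists, that also stood apart from the random lists. Other results that changed sides count as moved, or as within their interval. Of 2352 gene folds (237 results), 1932 stayed within their interval, 405 moved outside it with no turn counted and 15 turned. Of 4492 list medians (379 results) these numbers were 3614, 845 and 33, of 384 share ratios (34 results) 264, 104 and 16, of 24 counts of nuclei 5, 19 and 0, and of 116 shares of nuclei with a UMI 31, 85 and 0. CPM over all genes left all 237 folds and 379 medians within their interval, as at most 1% mitochondrial UMIs did for the 34 share ratios and 4 counts of nuclei, no doublets removed for the 34 share ratios, and no second clustering for the 33 share ratios it gave. For the values that follow, the cause was not tested, except that the floors, the doublet settings and all kept nuclei change the number of nuclei by construction, and added counts pull folds on few UMIs toward 1.

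With the floor of 300 genes, 79557, 21253, 53871 and 68461 barcodes passed from sham to 72 h. The doublet rule removes a share that rises with the number called, most in sham, and left 28922, 17639, 30654 and 30966. Nuclei from sham to 72 h numbered 9168, 8350, 8305 and 7259 with the order-of-magnitude rule, 14705, 12545, 13559 and 11238 with no doublets removed, and 13987, 11846, 12741 and 10616 with the automatic threshold. With the floor of 1000 genes they numbered 11817 in sham, 11855 at 24 h and 9921 at 72 h. Oligodendrocyte share ratios at 6, 24 and 72 h were 1.19, 1.00 and 0.884 with the order-of-magnitude rule, 0.931, 1.12 and 0.772 with the automatic threshold, 0.963, 1.01 and 0.644 with each library clustered alone and 1.64, 1.99 and 1.21 over all kept nuclei. At 6 and 24 h they were 1.35 and 1.602 with the floor of 1000, 0.0514 and 0.0656 with the other ranking and 1.35 and 1.59 with the 72 h baseline, and 1.37 at 6 h at resolution 0.5. Microglia share ratios were 0.0223, 0.596 and 0.718 with the order-of-magnitude rule and 0.00252, 0.0225 and 1.07 at resolution 0.5. At 24 and 72 h they were 1.15 and 1.49 with the automatic threshold and 1.21 and 1.51 over all kept nuclei. At 6 and 24 h they were 0.00338 and 0.0255 with the other ranking and 0.153 and 0.775 with the 72 h baseline, and at 6 h 0.0749 with each library clustered alone and 0.662 with cluster 29 as microglia. Inhibitory ratios turned to 0.881 at 6 h at resolution 2.0, to 1.49 and 1.28 at 24 and 72 h with each library clustered alone, and at 24 h to 1.45 with the other ranking and 1.17 with the 72 h baseline. The T or NK cell ratio at 24 h turned to 1.12 with the other ranking and 1.64 with the 72 h baseline, and the precursor ratio at 6 h to 0.904 with that baseline.

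Cytokine medians in microglia at 6 h were 1.65 with each library clustered alone, 2.16 with median-of-ratios scaling, 2.83 after thinning, 4.28 with cluster 29 and 3.63 with the 72 h baseline, which gave 2.60 at 24 h. Interferon medians in oligodendrocytes were 3.48 and 3.11 at 6 and 24 h with the 72 h baseline, and 1.97 at 24 h with 5 added counts. Homeostatic medians in microglia at 72 h were 0.72 and 0.74 with the first and second free RNA profile, and the cell cycle median there -1.22 with the second. Complement and MHC in oligodendrocytes at 24 h turned to 0.22 with no doublets removed, 0.72 and 0.19 with the 2 profiles, 0.13 after thinning and 0.36 with the 72 h baseline, which gave -0.11 in microglia at 24 h. Complement and MHC in astrocytes at 6 h turned to -0.85 with no minimum count. Immediate early genes at 6 h turned with the 72 h baseline to 0.14 in D1-type, 0.34 in excitatory and 0.77 in inhibitory nuclei, and at 24 h to 0.79, 0.52 and 0.67. They turned in inhibitory nuclei to 0.17 at 24 h with the first profile and to 0.90 and 0.17 at 6 and 24 h with the second, which also gave 0.35 in oligodendrocytes at 72 h. Cell cycle genes in precursors turned to 0.15 and 0.75 at 6 and 24 h with the 72 h baseline. Ferroptosis turned to -0.090 in excitatory nuclei at 24 h with the first profile, and in oligodendrocytes at 72 h to 0.12 with the second and 0.048 after thinning. With the first profile, p53 genes turned to 0.18 in excitatory nuclei at 72 h, oxidative phosphorylation to -1.33 and ribosomal genes to -7.55 in excitatory nuclei at 24 h, and ribosomal genes to 0.65 in D1-type nuclei at 72 h. Ribosomal genes turned to -0.14 in oligodendrocytes at 6 h with each library clustered alone, and in astrocytes at 6 h to -0.18 after thinning and -0.35 with 5 added counts. Iron genes in oligodendrocytes at 24 h turned to -0.026 with each library clustered alone, neuronal injury genes in D1-type nuclei at 72 h to 0.0058 after thinning, and D1 identity genes to -0.041 at 6 h with the floor of 1000 and to -0.019 at 72 h in matched clusters.

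Gene folds that turned were, at 6 h, Lef1 0.504 in matched clusters, and Egr2 1.66 and Btg2 1.27 in excitatory nuclei with the 72 h baseline. At 24 h they were Mrvi1 0.755 with each library clustered alone and 0.746 in matched clusters, Lhx9 0.994 in matched clusters, and with the 72 h baseline Egr2 1.44, Fosb 1.62 and Egr3 1.02 in excitatory, Fosl2 1.20 in D1-type and Fhl5 0.853 in inhibitory nuclei. At 72 h they were Cxcl10 in astrocytes at 0.452 with no doublets removed and 0.484 with each library clustered alone, Gpnmb in microglia at 0.585 with no doublets removed, and Fos in D1-type nuclei at 6.71 with the first profile.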

Other observations

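No test is reported in this part, and the clusters and lists given here were chosen after their values were seen.

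A cluster without a class name, 29, held 416 nuclei at 6 h and 8 at 24 h, and resembled strongly activated myeloid cells. Its nuclei at 6 h held Ccl4 at 5993 CPM, Ccl3 at 4436, Cxcl10 at 4285, Ccl5 at 4172, Il12b at 3874, Tnf at 1681, Il1b at 767 and Il6 at 359. Acod1, which makes the metabolite itaconate, stood at 1551 CPM, Slc7a11 at 5699 and Hmox1 at 523. Some microglia genes lay between microglia-like and excitatory neuron-like nuclei at 6 h: Csf1r at 226 against 701 and 0.807 CPM, Cx3cr1 at 92.2 against 433 and 9.23, and Tmem119, with 9 UMIs, at 8.22 against 44.4 and 0.0527. P2ry12, at 52.0 CPM against 219.6 in microglia-like nuclei, was not above the 67.9 of excitatory neuron-like nuclei. Csf3r likewise stood at 168 CPM against 437 and 0.614, while Mrc1 stood at 14.6 against 13.3 in microglia-like nuclei, Ccr2 had 1 UMI, and S100a8 and S100a9 were listed at 0. Clusters 17 and 36, also unnamed, held 2.94%, 1.28%, 1.497% and 2.75% and 0.493%, 0.656%, 0.538% and 0.518% of kept nuclei from sham to 72 h. The unnamed nuclei parted from cluster 25 fell in 2 clusters, with 82 and 36 nuclei in sham, 0 and 0 at 6 h, 2 and 1 at 24 h and 0 and 13 at 72 h.

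Glucocorticoid response genes were higher in every glial class at 6 h: their medians were 2.47 in oligodendrocyte-like, 2.43 in precursor-like, 1.995 (1.64 to 2.27) in microglia-like and 1.96 (1.38 to 2.57) in astrocyte-like nuclei, against 0.40 in excitatory and 0.32 in inhibitory neuron-like nuclei. Integrated stress response genes had a median of 1.45 (0.95 to 2.03) in microglia-like and 0.68 (0.43 to 0.84) in excitatory neuron-like nuclei at 6 h. Ferroptosis genes stood at 0.92 (0.48 to 1.10) and 0.78 (0.49 to 0.92) in microglia-like nuclei at 6 and 24 h, and heat shock genes at 0.64 (0.56 to 0.76) in oligodendrocyte-like nuclei at 6 h. Pyroptosis and necroptosis genes had a median of 1.49 (0.96 to 1.997) over 6 genes in astrocyte-like nuclei at 6 h, p53 and apoptosis genes 0.81 (0.61 to 1.52) in precursor-like nuclei, and complement and MHC genes 1.90 (1.64 to 2.62) over 7 genes in astrocyte-like nuclei, but -0.85 with no minimum count per gene. Astrocyte homeostatic genes stood at 0.38 (0.26 to 0.46), 0.11 (0.04 to 0.25) and 0.35 (0.27 to 0.56) at 6, 24 and 72 h, and matrix genes at 0.32 (-0.14 to 0.76), 0.48 (-0.09 to 0.97) and 0.01 (-0.47 to 0.22).

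In macrophage-like nuclei at 72 h, hypoxia and glycolysis genes had a median of -0.78 (-1.31 to -0.60), with 12 of 17 over 1.5-fold lower and 0 higher, cytokine genes -0.93 (-1.84 to -0.61), with 7 of 10 lower and 2 higher, and lipid and lysosome genes 0.55 (0.34 to 0.74). In neurons, glutamate receptor genes had medians of -0.22 (-0.27 to -0.21) in excitatory and -0.28 (-0.31 to -0.26) in inhibitory neuron-like nuclei at 6 h, and ion channel genes -0.06 (-0.08 to -0.05) in excitatory. Spiny projection neuron identity genes stood at 0.17 (0.11 to 0.19) in D1-type nuclei, or -0.041 with the floor of 1000 genes, and at -0.02 (-0.04 to 0.01) in D2-type nuclei at 6 h, and at 24 h at -0.10 (-0.13 to -0.09) and -0.06 (-0.07 to -0.02). Neuronal injury genes stood at -0.34 (-0.45 to -0.23) in D1-type nuclei at 72 h, or 0.0058 after thinning, and at 0.26 (0.08 to 0.52) at 24 h. Oxidative phosphorylation genes stood at 0.49 (0.44 to 0.54) in excitatory neuron-like nuclei at 6 h. Ribosomal protein genes stood higher at 24 h in each of the 10 classes compared there, from 0.45 (0.07 to 0.78) in neuroblast-like to 1.07 (0.42 to 1.33) in astrocyte-like nuclei, but the planned subtraction of free RNA turned the excitatory neuron value to -7.55. Cell cycle genes of precursor-like nuclei stood at -1.86 (-2.07 to -1.38), -1.59 and -2.04 at 6, 24 and 72 h, and at 0.15 and 0.75 at 6 and 24 h with the 72 h baseline.

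Mitochondrially encoded genes made up medians of 0.0760%, 0.0607%, 0.1008% and 0.0601% of UMIs per nucleus from sham to 72 h, and summed to 2758, 1567, 2642 and 1273 CPM in the planned empty droplets of 10 to 100 UMIs, and to 3102, 4613, 8360.2 and 8006 CPM in the set added later. With the profile added later, the estimated share of free RNA from sham to 72 h was 20.4%, 13.7%, 12.1% and 11.9% in microglia-like, 13.4%, 7.37%, 7.08% and 9.70% in excitatory neuron-like and 20.01%, 10.55%, 11.2% and 11.8% in astrocyte-like nuclei. With the planned profile it was 25.3%, 16.7%, 16.7% and 13.6%, then 19.6%, 33.5%, 54.8% and 12.1%, and then 19.95%, 14.3%, 17.8% and 15.3% in these classes.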
